A study of Mus musculus with 2 samples.

How the data were processed

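MicroRNA-seq libraries of RNA under 30 nucleotides were made from pooled intestine of E16.5 mouse embryos, 1 library for each of 2 biological replicates, per the labels. The authors deposited raw read counts per miRNA gene, not normalized, for 1973 genes in each library, on the mm10 assembly with GENCODE annotation M4, per the readme of each library. The aligner, the counter, their versions and any adapter trimming are not given in the sources used here. Each table holds 3 columns of counts, without regard to strand and for each strand, and 4 leading rows that name no gene. The column names are not given in the tables. The columns were told apart by their values: the per-strand columns summed to the first in every gene row, and the column used here held over 96% of it. Reads that name no gene were left out of totals and tests: 19.5% and 17.2% of reads were unmapped in replicates 1 and 2, 26.2% and 25.7% mapped to several loci, 3.69% and 2.88% lay outside annotated miRNA genes, and 0 were ambiguous.

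The counts on the strand of the gene were divided by their total (4261976 and 5680764) to give CPM. Symbols, coordinates and hairpin sequences came from GENCODE M21 on the same assembly, in which 1894 of the 1973 identifiers were found; the other 79 held 2 counts. A RefSeq gene table of the same assembly was used for miRNA loci that have no row. Intervals are exact Clopper-Pearson 95% intervals per library, and the detection limit is 3 counts.

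Both libraries form 1 group, so edgeR's quasi-likelihood test, which needs a contrast and replicates on each side, was not used. Genes with at least 20 counts summed were compared between the replicates with an exact two-sided conditional binomial test, with the expected share from TMM effective library sizes (edgeR 4.0.16) and Benjamini-Hochberg adjustment at 0.05. Log2 ratios used a prior of 0.5 counts, and correlations a pseudocount of 1 CPM. The dispersion came from edgeR with an intercept only. List medians were placed among 10000 random lists of the same size drawn from 10 expression bins. Other computation used Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and R 4.3.3.

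The groups, tests, 16 gene lists and most alternatives were fixed before the data were examined. Genes were named by rule: the 20 with the highest mean CPM, up to 4 top members of each list, the 5 highest in each replicate by log2 ratio among those past the test at 100 CPM or more, and 16 genes of 7 chosen clusters. Alternatives were the unstranded counts, each replicate alone, the most abundant gene left out of the total, other count minimums (1, 100 and 200 counts, 1 CPM), pseudocounts of 0.1 and 10, DESeq2 1.42.0 size factors, total counts, and a 1.5-fold minimum. A 2-fold minimum, lists without their top member, and 1 gene per cluster were chosen after seeing the data. List members without a row were not analysed here. The lists overlap: 13 neural and 5 let-7 genes also belong to the list of genes with identical mature copies. The binomial test was tested on counts simulated for replicate 2 against replicate 1 over 364 genes. The counts were Poisson draws, with counting error only, and total counts took the place of TMM scaling. The test recovered 69.1% of genes changed 1.25-fold, 71.4% at 1.5-fold and 88.4% at 2-fold. Of the genes it called, 4 were unchanged (2.55% of calls). The simulation holds no spread between libraries, so it gives no rate of false calls for the real libraries.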

Results

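MicroRNAs were sequenced from the intestine of B6NCrl mouse embryos at embryonic day 16.5, as a pair of libraries from pooled male and female embryos. MicroRNAs are short RNAs cut from hairpin transcripts that repress messenger RNAs. The labels name both libraries as biological replicates of 1 group, from separate tissue samples, so the design holds no contrast between conditions and the comparisons are among miRNA genes and between the replicates. The pool of replicate 2 came from 41 embryos, and the number of embryos in the pool of replicate 1 is not given in the labels. Replicate 1 held 8747512 reads, of which 4261976 were counted on the strand of a miRNA gene (48.7%). Replicate 2 held 10876035 reads, of which 5680764 were so counted (52.2%). Levels are given as these counts divided by their total in each library and scaled to CPM, as mean ± SD of the libraries (n = 2), with coordinates on mm10. The limit used for a gene with 0 counts was 3 counts, or 0.704 CPM in replicate 1 and 0.528 CPM in replicate 2, a one-sided bound that lies below the upper end of the two-sided exact intervals. Intervals and these limits cover counting error only, since PCR copies of a molecule could not be told apart.

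The first question is which miRNAs make up the small RNA of the fetal intestine. Mir143, a miRNA of smooth muscle and other mesenchymal cells (chromosome 18, 61649196 to 61649258), was the most abundant gene in both libraries, at 173802 ± 4537 CPM or 17.4% ± 0.454 of the counts (n = 2). Its exact Clopper-Pearson 95% intervals were 176648 to 177373 CPM in replicate 1 and 170285 to 170904 CPM in replicate 2. The let-7 genes Mirlet7g (61466 ± 7000 CPM) and Mirlet7i (47038 ± 1824 CPM) followed, then Mir10a, which lies in the HoxB cluster (45403 ± 2553 CPM), and Mir335, which lies in the imprinted gene Mest (35281 ± 709 CPM). Mir26b (32837 ± 2540 CPM), the endothelial Mir126a (32188 ± 1983 CPM), the epithelial Mir429 (25905 ± 1936 CPM), Mir99a (24178 ± 1876 CPM) and the epithelial Mir215 (23894 ± 7648 CPM) completed the 10 most abundant genes. Mir143 stood 2.85 ± 0.398 times above Mirlet7g, a gap larger than the spread between the replicates. That spread does not measure a bias between sequences that both libraries share. These levels count only reads on the strand of the gene: the opposite-strand reads at Gm25301 (18054 ± 338 CPM) would rank 16. The levels, ranks and shares also leave out reads that mapped to several loci, 26.2% and 25.7% of reads in replicates 1 and 2. A miRNA with identical copies at several loci may therefore rank too low or be missing from the most abundant genes. The 10 genes held 50.2% ± 1.47 of the counts and the 20 most abundant 68.3% ± 1.43. Of 1973 genes, 347 had at least 10 counts in both libraries, 94 reached a mean of 1000 CPM, 23 reached 10000 CPM, and 1257 had 0 counts in both.

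**Figure D1:**
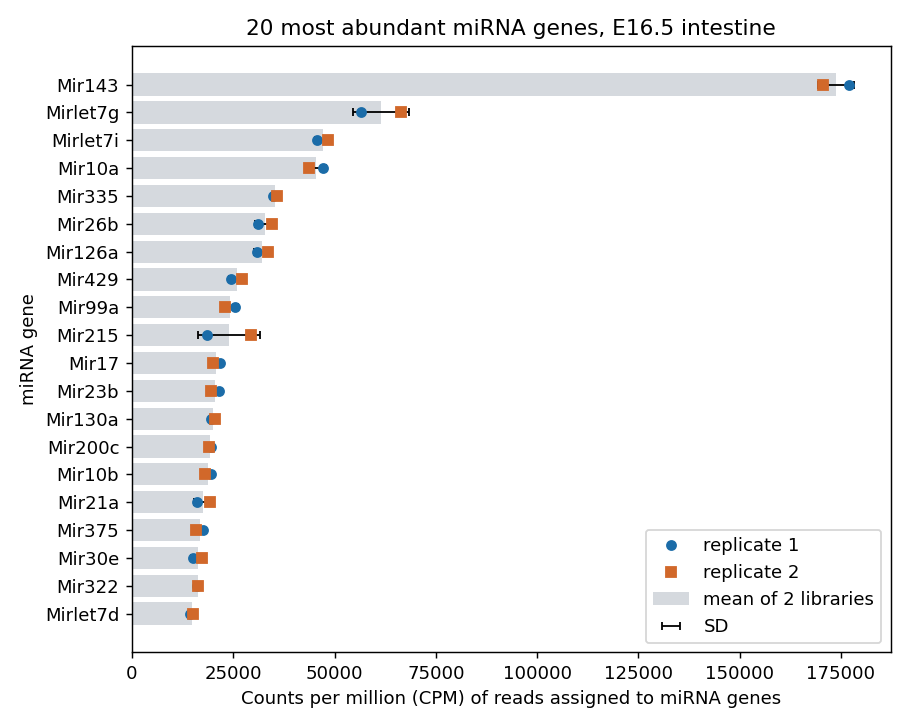
Levels in CPM (x axis) of the 20 most abundant miRNA genes (y axis) in E16.5 intestine; bars are means of 2 libraries that start at 0, lines are SDs, and circles and squares are replicates 1 and 2. Mir143 stands at 173802 CPM, and Mir215 shows the widest gap between the replicates, at 18486 and 29302 CPM.

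Epithelial miRNAs held a large share of the miRNA gene counts, which is not a share of cells or tissue. All 14 members of a list of miRNAs known from intestinal epithelium were detected, and together they held 12.9% ± 1.15 of the counts (n = 2). Of these, Mir106b is also counted in the miR-17/92 list. Mir194-1 and Mir194-2 have an identical mature copy elsewhere, and reads that mapped to several loci are outside the share. The miR-200 family, which maintains epithelial identity by repressing Zeb1 and Zeb2, was led by Mir429 (chromosome 4, 156053905 to 156053987) and by Mir200c on chromosome 6 (19151 ± 352 CPM). Mir375, known from endocrine cells, stood at 16685 ± 1355 CPM. Mir215 on chromosome 1 (185313581 to 185313692) and Mir192 on chromosome 19 carry nearly the same mature miRNA, and Mir215 was 3.18 ± 1.02 times as abundant as Mir192 (7510 ± 8.79 CPM). That ratio was 2.46 in replicate 1 and 3.91 in replicate 2.

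The mesenchymal list took a larger share of the counts than the epithelial list, but its share rested on 1 gene. Both shares leave out reads that mapped to several loci, so this order holds for the gene counts only. The 10 genes of the smooth muscle and mesenchyme list held 19.4% ± 0.605 of the counts, and Mir143 alone made up 89.8% of that. The next members were Mir100 (5718 ± 973 CPM), Mir214 (4586 ± 561 CPM) and Mir22 (3812 ± 413 CPM). Without Mir143 the list held 1.98% of the counts. Of the 10 genes, 2 have an identical mature copy elsewhere, and reads that mapped to several loci are outside their counts. Mir126a, which lies in the endothelial gene Egfl7 (chromosome 2, 26591357 to 26591429), was the only member of the endothelium list and held 3.22% ± 0.198.

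Hox-linked, let-7, miR-17/92 and imprinted miRNAs were all well represented. The 6 miRNA genes of the Hox clusters held 7.07% ± 0.439 of the counts, with Mir10a 2.41 ± 0.00418 times above Mir10b (18860 ± 1028 CPM), followed by Mir196b (5441 ± 684 CPM) and Mir615 (750.0 ± 68.9 CPM). The let-7 family, which accumulates as tissues mature, held 13.9% ± 0.984 over 10 genes, with Mirlet7d at 14702 ± 463 CPM and Mir98 at 9672 ± 570 CPM. Of the 10, 5 have an identical mature copy elsewhere, and the share leaves out reads that mapped to several loci and the opposite-strand reads at the loci of Mirlet7e (4785 ± 268 CPM) and Mirlet7f-1 (166 ± 1.49 CPM), which have no row here. The clusters of the proliferation-associated miR-17/92 family held 5.13% ± 0.177 over 15 genes, led by Mir17 (20824 ± 1267 CPM), Mir20a (9060 ± 432 CPM), Mir93 (7623 ± 344 CPM) and Mir106b (5049 ± 95 CPM). Of these 15 genes, 4 have an identical mature copy elsewhere, as do 2 of the 6 Hox genes. Reads that mapped to several loci are outside both shares. The imprinted Dlk1-Dio3 region of chromosome 12 held 5.53% ± 0.418, with 39 of 43 genes detected in both libraries and Mir411 (9499 ± 478 CPM), Mir127 (7368 ± 490 CPM), Mir487b (6443 ± 239 CPM) and Mir379 (4489 ± 5.76 CPM) the highest of the genes counted on their own strand. The share leaves out opposite-strand reads at the loci of Mir409 (4678 ± 293 CPM), Mir376a (3015 ± 263 CPM), Mir299a (1645 ± 51.7 CPM) and Mir380 (653 ± 32.7 CPM), which have no row here. The other imprinted miRNAs held 4.20% ± 0.0190, of which Mir335 made up 84.0%, ahead of Mir296 (2900 ± 209 CPM), Mir298 (2353 ± 375 CPM) and Mir483 (1294 ± 307 CPM).

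Markers of other cell types held few of the gene counts. For the neural and muscle lists this does not show low levels. Of the 15 neural genes 13, and 3 muscle genes, may lose reads that mapped to several loci. The neural list held 0.221% ± 0.0158, mostly from Mir137 (1542 ± 171 CPM), with Mir7-1 (187 ± 13.4 CPM), Mir138-1 (170 ± 2.12 CPM) and Mir138-2 (102 ± 10.9 CPM) below it. The blood list held 0.140% ± 0.0144, with the myeloid Mir223 at 777 ± 38.9 CPM, the erythroid Mir451a at 383 ± 79.6 CPM and Mir155 at 63.0 ± 10.1 CPM. Its member Mir142b had 0 counts on its own strand and 1400 ± 120 CPM on the opposite strand, above Mir223, and with unstranded counts the list held 0.270%. The hepatocyte miRNA Mir122 held 0.0721% ± 0.0386, and its level differed between the libraries (994 and 448 CPM). The pluripotent cell list held 0.0114% ± 0.00143, with Mir302a at 39.0 ± 2.19 CPM, Mir302d at 37.4 ± 2.15 CPM, Mir302b at 24.0 ± 2.86 CPM and Mir302c at 4.25 ± 3.28 CPM (6.57 and 1.94 CPM in replicates 1 and 2). The skeletal and cardiac muscle list held 0.0110% ± 0.00152, with Mir206 at 61.0 ± 1.63 CPM and Mir208b at 30.0 ± 7.18 CPM. The pancreas list held 0.00032% ± 0.00022, from 7 counts in replicate 1 and 27 in replicate 2 (0.000164% and 0.000475%). Of these lists, 13 neural and 3 muscle genes are on the list of genes with an identical mature copy elsewhere in the genome. That list was fixed beforehand and need not name every such gene. The 56 genes on it with a row had a median of 26.9 CPM, against 5152 CPM for a list of 28 single-copy genes that was not matched to them. Mir302a and Mir302b share a stretch of 20 bases with another gene, and reads that mapped to several loci are outside the counts of this list too.

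**Figure D2:**
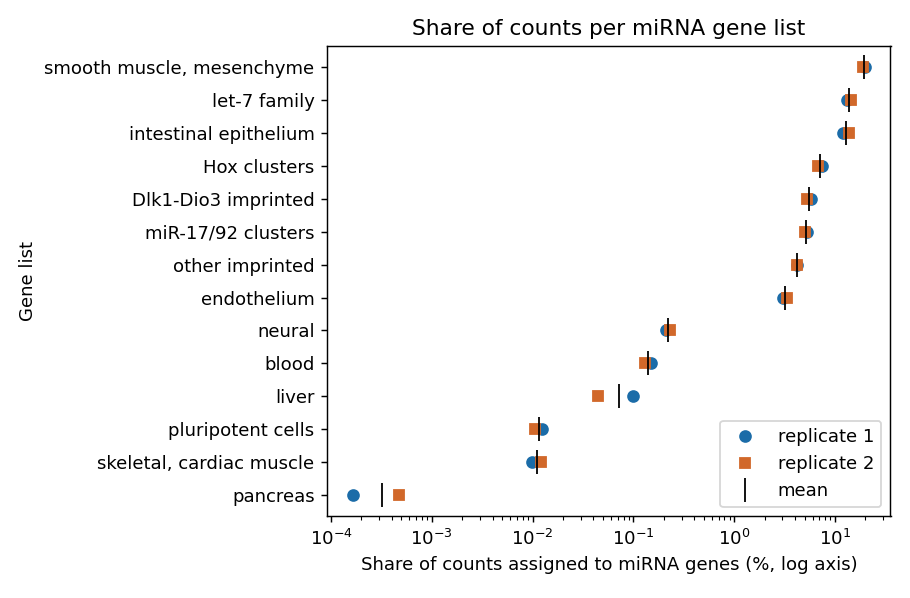
Share of all miRNA gene counts in percent on a log axis (x axis) for 14 gene lists (y axis); circles and squares are replicates 1 and 2 and ticks are their means. The smooth muscle and mesenchyme list stands highest at 19.4%. The liver list, which is Mir122 alone, and the pancreas list, from 7 and 27 counts, differ between the replicates.

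Genes that lie together in the genome often differed widely in level. Clusters of at least 2 genes on 1 strand less than 10 kb apart numbered 104 and held 58.1% ± 0.778 of the counts. Mir143 was 66.7 ± 6.92 times as abundant as its neighbour Mir145a (2622 ± 340 CPM). In the cluster of Mir429, that gene was 2.51 ± 0.0615 times above Mir200b, which was 5.63 ± 0.177 times above Mir200a. Mir200c was 5.74 ± 1.00 times above Mir141, Mir215 was 7.37 ± 0.693 times above Mir194-1, and Mir192 was 1.92 ± 0.370 times above Mir194-2. Mir451a was 2.63 ± 0.235 times above Mir144. Mir23a (11490 ± 619 CPM) was 58.1 ± 3.31 times above Mir27a and 62.4 ± 5.25 times above Mir24-2. Mir194-1, Mir194-2 and Mir24-2 have a mature copy at another locus, Mir23a and Mir27a share a stretch of 20 bases with another gene (as do Mir23b and Mir411), and reads that mapped to several loci are outside the gene counts. Each of these ratios exceeded 1 by more than the spread between the replicates. That spread does not measure a bias between sequences that both libraries share, so the ratios are of counts and not of molecules in the tissue.

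The remaining question is how far the replicates differed. Most epithelial miRNAs were higher in replicate 2 after TMM scaling: 13 of the 14 list members passed the test in that direction. Mir375 passed in the other (log2 ratio of replicate 2 to replicate 1 of -0.04). The test covers counting error only, and at these counts a ratio as small as that of Mir375 passes, so the number past it says little by itself. The 5 genes with the largest ratio among those past the test at 100 CPM or more were all of that list: Mir215 (0.79), Mir194-1 (0.60), Mir194-2 (0.52), Mir141 (0.45) and Mir802 (0.43). These are not independent, since Mir215 and Mir194-1 lie in 1 cluster, and Mir194-1 and Mir194-2 carry the same mature miRNA. Higher in replicate 1 were Mir122 (-1.02), Mir495 (-0.78), Mir350 (-0.72), Mir667 (-0.59) and Mir490 (-0.59), of which Mir495 and Mir667 belong to the Dlk1-Dio3 region. Of the 39 tested genes of that region, 23 were higher in replicate 1, 7 were higher in replicate 2 and 9 did not pass. With total counts in place of TMM scaling these numbers were 31, 0 and 8.

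Across 364 genes with at least 20 counts summed, the replicates had a Pearson r of 0.994 and a Spearman rho of 0.992 for log2(CPM + 1), computed across genes, which are not independent replicates, and a biological coefficient of variation of 14.9%. An exact two-sided binomial test on the counts, with Benjamini-Hochberg adjustment over the 364 genes, found 189 that differed by more than counting error, 89 higher in replicate 2 and 100 higher in replicate 1. With total counts in place of TMM scaling, which shifts all log2 ratios by 0.13, the numbers were 46 and 164, and with no filter on low counts 105 and 77. For Mir122 the adjusted p of the exact test was 1.65e-180 and for Mir215 the log2 ratio was 0.79 with a counting error of 0.01. These tests compare 2 libraries, not conditions. They treat reads as independent molecules and set the ratio against counting error only, not against the spread expected between pools. At this depth very small ratios pass: Mir10a passed at a log2 ratio of 0.01 (adjusted p of the exact test 0.00186). Passing is therefore no measure of the size of a difference. At least 1.5-fold differences were found for 40 genes.

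By list, the epithelial median log2 ratio was 0.32, at percentile 100 among 10000 random lists matched on expression, and all 14 members passed when adjusted over the list alone. With 1 gene kept per genomic cluster, 9 genes had a median of 0.28 at percentile 99.3. Under total counts 10 of all 14 members were higher in replicate 2. Mir375 (-0.17), Mir200c (-0.04) and Mir106b (-0.04) were higher in replicate 1, and Mir192 did not pass. The Dlk1-Dio3 median was -0.16 at percentile 0.04, and 30 of 39 genes passed when adjusted over the list alone. With 1 gene kept per genomic cluster it stood at percentile 32.0 over 3 genes. The muscle list had a median of 0.77 at percentile 99.96 over 4 members at low counts, of which Mir208b (0.62) and Mir499 (0.93) passed (2 adjusted over the list alone). In the let-7 list 7 of 10 genes were higher in replicate 2 (also 7 adjusted over the list alone), with a median of 0.21 at percentile 96.5, but under total counts 5 were higher and 3 lower, and with 1 gene per cluster the list stood at percentile 87.0. The medians of the neural (percentile 94.7), miR-17/92 (76.3), other imprinted (44.7), pluripotent cell (48.6), blood (28.1), mesenchyme (25.8) and Hox (7.80) lists lay inside the central 95% of random lists. Adjusted over the list alone, 2 neural, 8 miR-17/92, 3 other imprinted, 1 pluripotent cell, 2 blood, 8 mesenchymal and 4 Hox genes passed, against 2, 8, 3, 2, 2, 8 and 4 adjusted over all genes. These calls depended on the scaling: from TMM to total counts, the genes higher in replicate 2 and in replicate 1 went from 2 and 0 to 1 and 2 in the neural list, from 6 and 2 to 3 and 7 in miR-17/92, from 1 and 2 to 1 and 3 among other imprinted genes, from 1 and 1 to 1 and 5 in blood, from 3 and 5 to 2 and 6 in mesenchyme and from 2 and 2 to 0 and 5 in Hox, while the pluripotent cell list kept 0 and 2. The neural and miR-17/92 medians were positive under TMM and negative under total counts. Mir143 changed sign likewise (0.08 and -0.05), and the other imprinted median changed sign between TMM and DESeq2 size factors. With at least 200 counts summed, 2 medians that were negative turned positive. The mesenchyme median became 0.06 at percentile 75.2 over 9 genes, and the pluripotent cell median 5.46e-05 at percentile 76.0 over 3 genes. Single genes stood for endothelium (Mir126a, 0.26), liver (Mir122) and pancreas (Mir217, 2.10 from 4 and 23 counts), and each passed.

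**Figure D3:**
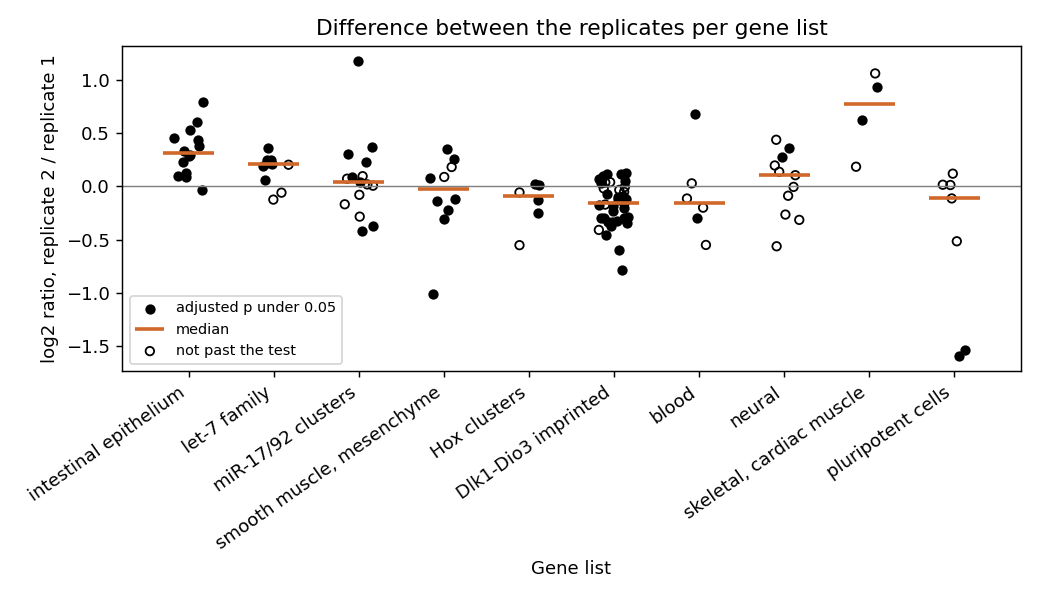
Log2 ratio of replicate 2 to replicate 1 after TMM scaling (y axis) for the tested members of 10 gene lists (x axis); each point is a gene, filled where the adjusted p of the exact binomial test was under 0.05, and lines are medians. The epithelial median is 0.32 and the Dlk1-Dio3 median -0.16, and under total counts all points lie 0.13 lower, which turns the sign of the neural and miR-17/92 medians.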

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

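The tests of the opposite-strand reads, of neighbour ratios and their control, of epithelium and of the depth and GC trends were chosen only after the results were seen; the ratio of list medians, the cluster permutation and the rank correlations with depth and GC were planned.

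Reads in the opposite-strand column, which the report uses only to mark what its levels leave out and in the unstranded alternative, were above the limit of 3 counts in 10 genes that had almost none on their own strand. In replicate 2 they numbered 101205 at Gm25301, 26106 at Gm25927, 25397 at Gm24321, 19232 at Gm24083, 18184 at Gm25252, 9135 at Mir299b, 8434 at Mir142b, 3577 at Gm25750, 2789 at Mir497b and 949 at Gm24111. These loci hold Mir378a, Mirlet7e, Mir409, Mir191, Mir376a, Mir299a, Mir142, Mir380, Mir497 and Mirlet7f-1 in RefSeq, none of which has a row here. The reads at Gm25301 (18054 ± 338 CPM, n = 2) would rank 16 among all genes.

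Against a loss of strand, the median opposite-strand share of 363 other genes was 0%, although Mir3074-1, which overlaps Mir24-1, reached 46.4%. A candidate explanation is that the reads belong to the miRNA encoded on the other strand: 10 of the 10 genes overlap a RefSeq miRNA without a row, against 27 of 1884 other genes (Fisher's exact p = 2.18e-18). The RefSeq table used gives no strand, so that the loci lie opposite was not read from it. No biological explanation was tested.

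Reads that map to several loci made up 25.9% ± 0.340 of each library (n = 2), outside every gene count. Genes whose mature miRNA has an identical copy elsewhere had a median of 26.9 CPM (56 genes). A list of 28 single-copy genes had a median of 5152 CPM, which gives a ratio of 0.00522. Of the 56, 53 share a stretch of 20 bases with another gene, against 5 of the 28. The lists were not matched: 13 neural and 3 muscle genes are among the 56, so the ratio does not isolate the effect of copies. The low median may reflect reads of identical copies left out of gene counts. Lower transcription of these loci cannot be told apart from it: the median ratio to the most abundant single-copy neighbour was 0.018 over 19 genes. A control of 10 single-copy genes came from only 3 clusters, with a median of 0.608. It includes the top gene of each cluster, Mir106a (1.13), Mir17 (2.30) and Mir23a (57.9), set against a less abundant neighbour. These ratios exceed 1 by construction and raise the median, so the 2 medians are not comparable. Of the 10 control genes, 3 also lay under 0.1, among them Mir27a, which shares 20 bases with another gene (12 of the 19; Fisher's exact p = 0.128). Mir194-2, Mir194-1, Mir92-1, Mirlet7f-2 and Mir16-1 were the multi-copy genes above 1000 CPM.

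The replicates differed by more than counting error in 189 genes. The planned rank correlations of the log2 ratio with depth and hairpin GC content, 0.216 and -0.154, lay between the bounds set for them and decided nothing. After a linear trend on mean expression was removed, 166 of the 189 remained past the test, and 158 after one on GC. With correlations this weak already seen, most genes were likely to remain. The removal therefore weighs only against a linear trend as the whole cause, and leaves a partial or other effect of depth or GC open. Neighbours in 40 clusters shifted together, with 0.53 of the variance between clusters against 0.28 for permuted genes (permutation p = 4e-05; 0.0023 without chromosome 12), so the differences may lie partly in whole transcripts. A different share of epithelium in the pools, a hypothesis drawn from the shift of that list, cannot be told apart from shifts of single genes: the members ranged from -0.04 for Mir375 to 0.79 for Mir215, and their SD on the log2 scale was 0.96 times that of 176 other genes (0.22 against 0.23), neither closer together nor farther apart than the bounds set. Differences in stage, dissection or pool size were not tested.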

How the results depend on the processing

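The 2-fold minimum, the lists without their top member and 1 gene per cluster were tests chosen only after the results were seen, as was the 1.5-fold limit for leaving out a replicate. No paired analysis was possible because there is 1 group only, and for the same reason other splits of the samples do not apply. TMM scaling moved 0 of 73 named gene levels by more than 1 SD, unstranded counts moved 13, and leaving Mir143 out of the total moved 56 of 72, as a smaller total must. The TMM factors (1.05 and 0.956) lower 1 library and raise the other, so a mean of both hardly moves by construction, and the 0 shows little. Leaving out a replicate always moves a mean of 2 by 0.707 SD, so that limit shows nothing there. By size, it moved 6 of the 73 by over 1.5 times: without replicates 1 and 2, Mir122 stood at 448 and 994 CPM, Mir302c at 1.94 and 6.57, Mir217 at 4.05 and 0.939, Mir208a at 2.82 and 1.41, Mir216a at 0.704 and 0.235, and Mir216b at 0 and 0.469.

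At least 1 count in both libraries gave 585 detected genes. The share of the 10 most abundant genes was 48.3% with unstranded counts and 42.2% with Mir143 left out. Leaving Mir143 out of the total gave shares of 15.7% for the epithelial list, 2.39% for mesenchyme, 8.56% for Hox, 0.0133% for muscle, 0.268% for neural, 0.169% for blood, 3.90% for endothelium, 16.8% for let-7, 6.21% for miR-17/92, 0.0139% for pluripotent cells, 6.69% for Dlk1-Dio3, 5.08% for other imprinted, 2.19% for multi-copy and 31.1% for single-copy genes. Leaving out the top member of each list gave, in that order without endothelium, 10.3%, 1.98%, 2.53%, 0.00490%, 0.0672%, 0.0622%, 7.73%, 3.04%, 0.00754%, 4.58%, 0.673%, 1.41% and 21.1%, and 7.04e-05% for pancreas. Unstranded counts gave 18.6% for mesenchyme, 0.270% for blood, which then includes the opposite-strand reads at Mir142b, 4.94% for miR-17/92, 4.04% for other imprinted, 1.74% for multi-copy and 24.7% for single-copy genes.

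With no filter Spearman's rho was 0.920. Genes that differed between the replicates numbered 40 at 1.5-fold (9 higher in replicate 2, 31 in replicate 1) and 23 at 2-fold (4 and 19), by construction fewer. Total counts gave 46 and 164, of which 160 in all were shared with the 189. The Dlk1-Dio3 list went to percentile 32.0 with 1 gene per cluster, which leaves 3 genes. The floor of 3 counts limits what can be said of genes under 0.704 CPM.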

Other observations

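No test in this part was chosen only after the result was seen.

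Beyond the lists, the X-linked cluster of Mir322 (16201 ± 76.2 CPM, n = 2), whose 7 genes were all detected, held 2.10% ± 0.0468 of the counts. Mir130a (20043 ± 614 CPM), Mir21a (17628 ± 2335 CPM), Mir30e (16264 ± 1584 CPM) and Mir23b (20488 ± 1473 CPM) were among the 20 most abundant genes without belonging to a cell type list. The Dlk1-Dio3 miRNAs formed a larger cluster by number: 34 genes between 109709060 and 109747960 on chromosome 12 held 3.99% ± 0.276, with 29 detected. The multi-copy list held 1.81% ± 0.0399 of the counts and the single-copy list 25.7% ± 0.251, and their median log2 ratios between the replicates lay at percentiles 92.1 and 47.3 of random lists. Of 45 multi-copy genes tested, 8 were higher in replicate 2 and 10 in replicate 1 (17 in all adjusted over the list alone), and of 28 single-copy genes 14 and 7 (22 in all adjusted over the list alone). Under total counts these were 4 and 17 multi-copy genes and 8 and 15 single-copy genes. Total counts lower the log2 ratio of every gene by the same amount, so this reversal of the single-copy calls is built in. The percentile among random lists cannot change with the scaling for the same reason. At percentile 47.3 the single-copy list showed no direction relative to other genes.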
